A study of Mus musculus with 72 samples.

How the data were processed

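RNA of SOL and TA from 36 mice was hybridised to 72 arrays, 1 array for each muscle of each animal. The deposited values were log2 signals that had been normalised together with RMA, per the submitters' processing notes, which give no version, and each probe set stands for 1 gene through its Entrez number. No step of the submitters was repeated, and no value was changed, filtered or scaled before the main tests. The table held 21225 probe sets, of which 20239 had 1 gene symbol in the array's annotation, 0 had several and 986 were not listed there and stay unnamed. The 20239 named genes were tested. All of them matched the RefSeq gene table of assembly GRCm38.p6, which was used for the order of genes along chromosomes, with no coordinates printed.

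Muscle, genotype, time and replicate letter were taken from the sample labels, as were the animals' identification numbers, whose series (BM3, BM2*, BM2) served as possible batches. The labels do not say what the series mean. Array medians ran from 6.67 to 6.84, values from 2.12 to 14.4, and the closest 2 arrays correlated with r = 0.996, so no array was a copy of another. The median SD within groups of 3 was 0.14 in SOL and 0.15 in TA. The number of arrays limits the precision.

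The tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. Genotype effects were tested in each muscle with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on 36 arrays with a term for each group of genotype and time, as the mean over the 6 times of mKO minus Ctrl. The tissue difference and its interaction with genotype were tested on the differences TA minus SOL within animals. Rhythm was tested with a cosine and a sine of a fixed 24 h period in each muscle and genotype, jointly by the moderated F test, and its amplitude is the distance from mean to peak in log2 units. Differences in rhythm between genotypes, and between muscles in Ctrl, were tested on the same terms. P values were adjusted by Benjamini and Hochberg over all genes of a test, with a threshold of 0.05. Effects at single times came from the same fit.

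Each SOL and TA array of the same number comes from the same animal, per the labels, and the deviations of such pairs from their group means correlated with a median r of 0.046 (from -0.197 to 0.352, over 0.1 in 11 of 36 pairs). The tissue tests use the pairs because the labels state them.

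For groups of genes, 26 lists were written from general knowledge, 9 of them markers of other cell types, with 372 distinct members, 345 of them measured. They are core clock, clock output, glucose uptake and glycogen, glycolysis, pyruvate dehydrogenase and its regulators, insulin signalling, fatty acid uptake and oxidation, lipid synthesis and storage, citrate cycle and respiratory chain, amino acid catabolism, slow fibre genes, fast fibre genes, denervation-responsive and neuromuscular junction genes, atrophy and autophagy, glucocorticoid-responsive genes, heat shock and temperature-responsive genes, immediate early genes, and markers of adipocytes, endothelium, fibroblasts and tendon, macrophages, lymphocytes and granulocytes, erythroid cells, Schwann cells, smooth muscle and satellite cells. Levels were tested with camera of limma, which compares a list with all other genes, with a preset correlation of 0.01 and again with an estimated one, adjusted over the 26 lists. Rhythm calls were tested with Fisher's exact test, one-sided. Some lists share genes, so their tests are not independent, and no list was tested without its shared genes. The glucocorticoid list shares Per1 with the core clock, Tsc22d3 with clock output, Pik3r1 and Foxo1 with insulin signalling, and Glul and Klf15 with amino acid catabolism. The fast fibre list shares Pgam2 and Gpd1 with glycolysis. A list of 30 liver genes was written after liver transcripts had been seen on 1 array.

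Genes named in the report are all members of the core clock and clock output lists, the 10 genes with the largest change in each direction among those past the threshold of each genotype effect and of the tissue difference, the 10 with the smallest p of each rhythm or interaction test, and for each other list up to 2 members per direction with the smallest p. Genes known only by a model name were counted and not named (54 of the 1436 genes called in SOL, 116 of 3000 in TA, 526 of 8690 between tissues and 16 of 549 in the interaction). Outside this rule Lancl1, Kansl1l, Mreg, Nnt, Alb, Serpina1a and Mup3 were chosen after their values were seen.

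Every limma test of single genes was first run on simulated data with each gene's spread in each muscle, with 200 of 20239 genes changed by 0.25, 0.5 or 1 log2 unit. The noise was drawn independently for each gene and array, without correlation among genes, batches or outlying arrays. The shares of false calls may therefore be higher on the real arrays. Fisher's tests of lists were not simulated. The smallest size, 0.25, lay above the median size of the real calls of the genotype effect (0.194 in SOL, 0.186 in TA). It also lay above the median amplitude of real rhythmic genes (0.208 to 0.245 over the groups), so recovery of smaller changes was not simulated. For the genotype effect in SOL 82.1%, 98.5% and 98.5% were recovered and 4.62% of calls were false, and in TA 80.6%, 94.0% and 98.5% with 5.21%. For the tissue difference the values were 76.1%, 98.5% and 100% with 7.58%, and for the interaction 40.3%, 97.0% and 100% with 5.95%. For rhythm they were 76.1%, 92.5% and 100% with 5.29% in SOL of Ctrl, 71.6%, 95.5% and 100% with 8.72% in SOL of mKO, 68.7%, 94.0% and 100% with 6.42% in TA of Ctrl, and 70.1%, 94.0% and 100% with 5.38% in TA of mKO, with a median error of the peak between 0.194 and 0.229 h. For rhythm differing by genotype they were 44.8%, 97.0% and 100% with 4.17% in SOL and 32.8%, 88.1% and 100% with 5.16% in TA, and for rhythm differing by muscle 37.3%, 94.0% and 98.5% with 4.38%. In a simulation of the genotype effect in SOL, camera called the 1 list that had been shifted and 1 of 25 others.

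The alternatives were all probe sets in place of named genes, time as a factor of 6 levels in place of the cosine, leaving out each of the 36 animals in turn, only BM3 animals, only BM2 and BM2* animals, leaving out ZT20, the identification series as a block, the replicate letter as a block, 72 arrays without the pairing of muscles, 72 arrays in 1 fit with animal as a random block, fits on the 18 arrays of a group alone, eBayes with trend and robust options, array weights, only genes above the median level, array medians set to 0, and quantile normalisation over the 72 arrays. Leaving out the TA array with liver transcripts, and leaving out 4 TA arrays far from the rest of their groups (Ctrl ZT0 A, Ctrl ZT0 C, Ctrl ZT8 C and mKO ZT0 C), were added after the data had been seen. Other splits of the samples were drawn 100 times with the real split included. Random lists of the same size, matched on mean level in 100 bins, were drawn 10000 times. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15. No sample was left out of the main tests, and no promoter binding, protein or physiological measurement was analysed here.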

Results

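Transcript levels were measured with 72 whole-transcript arrays in the soleus (SOL), a slow postural muscle, and the tibialis anterior (TA), a fast muscle, of 36 male C57BL/6 mice aged 5 months. The mice were muscle-specific Bmal1 knockouts (mKO), in which a Cre recombinase under a fast myosin light chain promoter acts on floxed Bmal1 in muscle fibres, or Cre-negative littermates (Ctrl), with 18 animals per genotype. Both muscles of each animal were collected at 1 of 6 Zeitgeber times (ZT), 4 h apart, with lights on at ZT0 and off at ZT12, which gave 24 groups of 3 arrays. Values were on a log2 scale, with array medians between 6.67 and 6.84, and the number of arrays limits the precision. The animals carried 3 series of identification numbers, BM3 (23 animals), BM2* (7) and BM2 (6), which were treated as possible batches. The comparisons asked what muscle loses or gains in level and in daily rhythm in mKO, and whether slow and fast muscle differ in this. Because Ctrl animals had no Cre, an effect of Cre itself cannot be told apart from the loss of Bmal1.

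The transcript of the targeted gene Arntl, which encodes Bmal1, showed no called change of its mean level over all animals and lost much of its daily swing. Its mean was 7.81 in SOL of Ctrl and 7.90 in SOL of mKO, a difference of 0.092 ± 0.060 log2 units (SE, n = 18 animals per genotype, limma adjusted p = 0.508), and mKO was higher at 4 of 6 times. In TA the means were 8.21 and 8.14, a difference of -0.072 ± 0.059 (adjusted p = 0.465), with mKO higher at 3 of 6 times. Within the identification series, which differ in the times they hold, Arntl differed by 0.73 in SOL and 0.71 in TA among BM2 and BM2* animals and by -0.27 and -0.47 among BM3 animals, all but the -0.27 past the threshold. In SOL of Ctrl the level ran from 9.11 at ZT0 through 8.83 at ZT4, 7.29 at ZT8, 6.56 at ZT12 and 6.96 at ZT16 to 8.12 at ZT20 (means, n = 3). In SOL of mKO the same times gave 8.44, 8.33, 7.69, 7.33, 7.51 and 8.13. In TA of Ctrl they gave 9.22, 8.96, 7.63, 7.01, 7.83 and 8.62, and in TA of mKO 8.32, 8.19, 7.89, 7.71, 8.29 and 8.43. Arntl was thus lower in mKO at ZT0, by -0.67 in SOL (limma adjusted p = 0.0211) and -0.90 in TA (adjusted p = 0.000246), and higher at ZT12, by 0.78 in SOL (adjusted p = 0.00352) and 0.70 in TA (adjusted p = 0.00377). The amplitude of its rhythm was 1.34 in SOL of Ctrl and 0.59 in SOL of mKO (limma adjusted p of the difference = 1.33e-05), and 1.09 and 0.33 in TA (adjusted p = 1.7e-05). Where the probes lie relative to the floxed part is not given in the sources used here, so this transcript does not check the deletion.

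**Figure D1:**
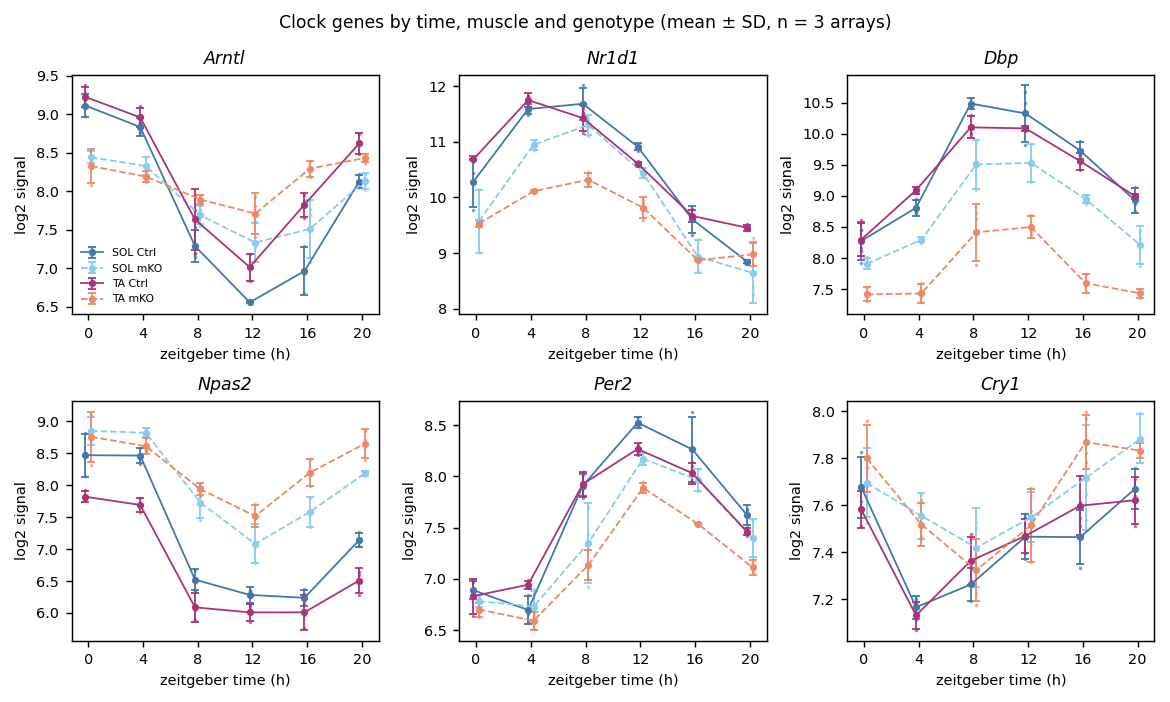
Log2 level of clock genes over the 6 Zeitgeber times (h) in SOL and TA of Ctrl and mKO, with points for single arrays and lines through the means of 3 animals (bars, SD). Arntl swings between 9.11 and 6.56 in SOL of Ctrl and between 8.44 and 7.33 in SOL of mKO.

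In SOL, the knockout went with a strong rise of Cdkn1a and a strong fall of Mylk4. Cdkn1a, which encodes the cell-cycle inhibitor p21, was higher in mKO by 2.26 ± 0.078 log2 units (SE, n = 18 animals per genotype, limma adjusted p = 4.33e-19), or 4.79-fold. Mylk4, which encodes a myosin light chain kinase, was lower by -2.33 ± 0.11 (adjusted p = 9.85e-16). Both moved in that direction at all 6 times. Of 20239 genes, 720 were higher and 716 lower in mKO at an adjusted p under 0.05, and 1176 of these 1436 genes had the same direction at every one of the 6 times. The median size among them was 0.19, with 4 genes over 2-fold higher and 2 over 2-fold lower.

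Of the genes that rose most in SOL after Cdkn1a, Slc1a1, a glutamate transporter gene, rose by 1.39 ± 0.077 (limma adjusted p = 2.04e-14). Mrln, which encodes the calcium pump inhibitor myoregulin, rose by 1.14 ± 0.051 (adjusted p = 4.75e-16), and Kcng4, a potassium channel subunit gene, by 1.07 ± 0.063 (adjusted p = 6.5e-14). Pln, which encodes the calcium pump inhibitor phospholamban, rose by 0.87 ± 0.16 (adjusted p = 0.000461) and Calb1, which encodes the calcium-binding calbindin, by 0.88. Olfm1, an olfactomedin gene, rose by 0.98, Tmem171, a membrane protein gene, by 0.93 and Pla2g7, which encodes a phospholipase that inactivates platelet-activating factor, by 0.88. Among the genes that fell, Mettl21e, a methyltransferase gene, changed by -1.03, Ctxn3, a cortexin gene, by -0.92, the Wnt antagonist gene Dkk2 by -0.92, the bicarbonate transporter gene Slc4a4 by -0.91 and the aspartoacylase gene Aspa by -0.89. Tbc1d1, whose product controls the movement of glucose transporters to the cell surface, fell by 0.88 ± 0.043 (adjusted p = 1.52e-15). Nos1, which encodes the neuronal nitric oxide synthase of the fibre membrane, changed by -0.88, and Asb15, an ankyrin repeat gene, by -0.84. Each of these genes had its direction at all 6 times.

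Among the 15 core clock genes measured in SOL, 3 rose, 8 fell and 4 were not called (3 and 9 when adjusted over the list alone). Clock, the partner of Bmal1, rose by 0.55 ± 0.031 (limma adjusted p = 1.9e-14), its paralogue Npas2 by 0.85 ± 0.062 (adjusted p = 1e-11) and the repressor Cry1 by 0.18. The repressors Nr1d2, Nr1d1 and Per3 fell by 0.82, 0.51 and 0.57. Per2, Rora, Ciart, Bhlhe40 and Bhlhe41 changed by -0.25, -0.25, -0.48, -0.38 and -0.68. Per1 (-0.20, adjusted p = 0.231), Cry2 (-0.011, adjusted p = 0.982) and Rorb (-0.021) were not called. The whole list stood below other genes (camera adjusted p = 0.00256, adjusted p = 0.267 with an estimated correlation). Of 11 clock output genes, 8 fell and 1 rose (8 and 2 when adjusted over the list alone; camera adjusted p = 1.8e-07, adjusted p = 0.0039 with an estimated correlation). The transcription factor genes Dbp, Hlf and Tef fell by 0.69, 0.60 and 0.41, the coenzyme Q gene Coq10b by 0.46, the kinase gene Wee1 by 0.33, Nampt, which makes a precursor of NAD, by 0.22, Tsc22d3 by 0.22 and the deubiquitinase gene Usp2 by 0.19. The repressor Nfil3 rose by 0.61, and Leo1 (0.15, adjusted p = 0.0816) and Tspo2 (0.097) were not called.

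Some genes of glucose use changed in SOL. Of 20 genes of glucose uptake and glycogen, 5 fell, 1 rose and 14 were not called (6 and 1 when adjusted over the list alone; camera adjusted p = 0.000364, adjusted p = 0.076 with an estimated correlation), with Pgm1 at -0.25 beside Tbc1d1 and a rise of 0.34 in Ppp1r3c, which targets phosphatase to glycogen. Of 14 genes of glycolysis, 6 fell and 1 rose (7 and 3 when adjusted over the list alone; camera adjusted p = 0.000364, adjusted p = 0.0579 with an estimated correlation), among them Pfkfb3 (-0.48), Pfkm (-0.20) and Eno3 (-0.16). The citrate cycle and respiratory chain stood above other genes (camera adjusted p = 0.0276, adjusted p = 0.572 with an estimated correlation), with 2 of 24 genes higher and the same 2 when adjusted over the list alone, and a median of 0.035. Leaving out single animals gave 4 to 8 called lists, and genes above the median level alone gave 3, against 5 with all animals and genes.

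Other lists were not called as wholes in SOL, while single members changed. In the pyruvate dehydrogenase list (2 rose and 1 fell of 12) Pdp1 fell by 0.39 and Pdk4 rose by 0.32, and in insulin signalling (6 and 3 of 22) Pik3ca rose by 0.39 and Akt1 fell by 0.24. In lipid synthesis and storage (2 and 2 of 20) the triglyceride synthesis gene Dgat2 fell by 0.77 and the lipid droplet gene Plin5 rose by 0.44. In amino acid catabolism (1 and 3 of 16) Gpt rose by 0.47 and Gpt2 fell by 0.61, and in fatty acid uptake and oxidation (2 and 1 of 22) Slc25a20 fell by 0.16. Of the fast fibre genes 1 rose and 5 fell of 15, with Mylpf at 0.42 and Myoz1 at -0.33, and of the slow fibre genes 2 rose and 5 fell of 13, with Casq2, which encodes a calcium store protein, at 0.66 and Tpm3 at -0.20. Of the denervation-responsive and neuromuscular junction genes 5 rose and 2 fell of 17, with the acetylcholine receptor gene Chrnb1 at 0.70, the synaptic collagen gene Colq at 0.55 and Chrna1 at -0.30. The growth inhibitor gene Mstn, in the atrophy list (1 of 17 fell), fell by 0.57, the glucocorticoid-responsive Sgk1 by 0.45 (2 rose and 5 fell of 16), and the immediate early genes Nr4a1 and Nr4a3 by 0.39 and 0.34 (2 of 16 fell). Among 15 heat shock genes 3 rose, with Hspa1a at 0.34 and Bag3 at 0.18. Camera adjusted p ran from 0.0661 to 0.712 over the 21 lists not called in SOL. The median, mean and test differed in sign for the slow fibre, glucocorticoid, insulin signalling and erythroid lists.

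Markers of other cell types in SOL were mostly not called. The endothelial list had a camera adjusted p of 0.0661 and 1 of 9 genes higher (Kdr, 0.22), the fibroblast and tendon list 0.094 with Scx at 0.28 and Fmod at -0.30 among 11 (1 higher and 4 lower when adjusted over the list alone, median -0.10), and the Schwann cell list 0.186 with Mbp at -0.28 among 5. No member of the adipocyte (camera adjusted p = 0.427), macrophage (0.577), lymphocyte and granulocyte (0.577), erythroid (0.577), smooth muscle (0.434) or satellite cell (0.592) lists passed the threshold of limma, and their counts at an unadjusted p under 0.05 were 0, 0, 0, 1, 0 and 0 in that order.

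Within the BM3 animals alone (23 arrays) all 1436 genes called in SOL kept the sign of their change, and 239 genes were higher and 340 lower. These genes were chosen on arrays that include the 23, which favours the same sign. Within the BM2 and BM2* animals (13 arrays) 1417 of the 1436 kept it, and 86 were higher and 81 lower.

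In TA the change was led by Cdkn1a, which rose, and Ces1d, which fell. Cdkn1a was higher in mKO by 2.85 ± 0.088 (SE, n = 18 animals per genotype, limma adjusted p = 2.61e-20), or 7.22-fold, and Ces1d, which encodes a carboxylesterase that splits triglycerides, lower by -2.80 ± 0.11 (adjusted p = 4.13e-18). Both had their direction at all 6 times. In all, 1369 genes were higher and 1631 lower (2773 and 2615 with array weights), and 2478 of the 3000 genes had the same direction at every one of the 6 times. The median size was 0.19, with 23 genes over 2-fold higher and 27 over 2-fold lower. In the Ctrl array of ZT0 replicate A, transcripts of liver genes were a median 4.27 log2 units above the other arrays of its group, and without this array 1225 genes were higher and 1476 lower.

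Of the genes that rose most in TA after Cdkn1a, the serine protease gene Prss55 rose by 2.78 ± 0.091 (limma adjusted p = 6.92e-20), the cardiac actin gene Actc1 by 1.501 ± 0.10 (adjusted p = 3.19e-12) and Casq2 by 1.35 ± 0.070 (adjusted p = 3.11e-15). The immunoglobulin heavy chain gene Ighm rose by 1.66, the tubulin-modifying Ttll7 by 1.31, the phosphatase gene Dupd1 by 1.31, Mrln by 1.28 and Tead4, a transcription factor gene of the Hippo pathway, by 1.24. Of the genes that fell, Car3, which encodes a carbonic anhydrase abundant in slow fibres and fat, fell by 1.71 ± 0.068 (adjusted p = 7.24e-18), and the transcriptional repressor gene Aebp1 by 1.63 ± 0.037 (adjusted p = 2.35e-23). The monoamine oxidase gene Maob changed by -1.58, Nkain1, whose product binds the sodium pump, by -1.57, the cytokine receptor gene Cntfr by -1.52, the caspase gene Casp12 by -1.35 and the adaptor gene Sorbs3 by -1.33. Each of these genes had its direction at all 6 times.

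Of the 15 core clock genes in TA 3 rose and 10 fell, also when adjusted over the list alone (camera adjusted p = 5.99e-10, adjusted p = 0.00245 with an estimated correlation). Npas2 rose by 1.59 ± 0.066 (limma adjusted p = 1.79e-17), Clock by 0.72 ± 0.050 (adjusted p = 2.39e-12) and Cry1 by 0.18. Nr1d2 fell by 1.53 ± 0.050 (adjusted p = 6.92e-20), Bhlhe40 by 1.11, Per3 by 1.02, Nr1d1 by 0.99, Ciart by 0.90, Per1 by 0.67, Rora by 0.48, Per2 by 0.42, Bhlhe41 by 0.30 and Cry2 by 0.18. Of the 11 clock output genes 8 fell and 2 rose (8 and 3 when adjusted over the list alone; camera adjusted p = 1.53e-10, adjusted p = 0.00027 with an estimated correlation). Dbp fell by 1.56 ± 0.061 (adjusted p = 6.17e-18), Hlf by 1.10, Coq10b by 0.72, Tef by 0.66, Wee1 by 0.64, Usp2 by 0.61, Tsc22d3 by 0.51 and Nampt by 0.32, while Nfil3 rose by 0.71 and Leo1 by 0.34.

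In TA, glucose uptake and glycogen genes stood below other genes, with 7 lower and 1 higher of 20 (10 and 1 when adjusted over the list alone; camera adjusted p = 2.29e-06, adjusted p = 0.0213 with an estimated correlation). The glucose transporter gene Slc2a3 fell by 1.03 ± 0.064, Tbc1d1 by 0.71 and Pgm1 by 0.22, and Ppp1r3c rose by 0.36. Genes of the citrate cycle and respiratory chain were higher, 8 of 24 against 1 lower (9 and 1 when adjusted over the list alone; camera adjusted p = 0.00895, adjusted p = 0.479 with an estimated correlation), with Cox5a at 0.19 and Idh2 at -0.22. Slow fibre genes were higher, 5 of 13 by either adjustment (camera adjusted p = 0.00895, adjusted p = 0.479 with an estimated correlation), with Csrp3 at 1.17 and Myoz2 at 0.81 beside Casq2. The slow isoform genes were mixed. In TA mKO was higher at 6 of 6 times for Tpm3, 5 for Myl3 and Myh7b and 4 for Myl2, Myh7 and Tnnc1. It was higher at 3 times for Tnni1 and Tnnt1 and at 1 for Atp2a2. Atrophy and autophagy genes were lower, 4 of 17 (5 lower and 2 higher when adjusted over the list alone; camera adjusted p = 0.0168, adjusted p = 0.479 with an estimated correlation), with Mstn at -0.35 and Map1lc3a at -0.27. Glucocorticoid-responsive genes were lower, 7 of 16 against 1 higher (8 and 2 when adjusted over the list alone; camera adjusted p = 0.0154, adjusted p = 0.479 with an estimated correlation), with a median of -0.073 and a mean of 0.0054 that Cdkn1a, a member, raised above 0. Per1, Tsc22d3 and Glul of this list, which fell in TA, also stand in the core clock, clock output and amino acid lists. Leaving out single animals gave 7 or 8 called lists, against 8 with all animals.

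The lists not called in TA held single changed genes. In glycolysis (2 rose and 4 fell of 14) Ldhb rose by 0.43 and Pfkm fell by 0.21, in pyruvate dehydrogenase (2 and 1 of 12) Pdp1 fell by 0.47, and in insulin signalling (4 and 5 of 22) Pik3ca rose by 0.48, Igfbp5 fell by 0.54 and Akt1 fell by 0.41. Among BM2 and BM2* animals alone Ldhb was not called and had the other sign. In fatty acid uptake and oxidation (6 and 6 of 22) Acadm rose by 0.32 and Ppargc1a, a coactivator of oxidative metabolism, fell by 0.29. In lipid synthesis (4 and 7 of 20) Dgat2 fell by 1.05 and Plin5 rose by 0.60, and in amino acid catabolism (4 and 2 of 16) Gpt rose by 0.65 and the glutamine synthetase gene Glul fell by 0.97. In the fast fibre list (1 and 2 of 15) Mylpf rose by 0.27, in the neuromuscular junction list (5 and 2 of 17) Chrnb1 rose by 1.05 and Musk by 0.41, in the heat shock list (3 of 15 rose) Bag3 rose by 0.26, and among immediate early genes (1 and 3 of 16) Atf3 rose by 0.96 and Jun fell by 0.22. Camera adjusted p ran from 0.182 to 0.947 over the 18 lists not called in TA. The median and mean differed in sign for glycolysis, glucocorticoid-responsive, fast fibre, erythroid, Schwann cell and smooth muscle genes, and for immediate early genes both were above 0 while the test pointed down.

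Of the other cell types, the adipocyte list was called lower in TA (camera adjusted p = 0.0255, adjusted p = 0.479 with an estimated correlation). Car3 and Retn (-0.19) were the 2 of 9 members called, both lower (3 lower and 2 higher when adjusted over the list alone). The median was -0.081 and the mean -0.23, with Car3 the lowest at -1.71, and the list was not tested without Car3. Among BM2 and BM2* animals alone Retn was not called and had the other sign. Single members changed among fibroblast and tendon (Dcn, -0.15) and satellite cell markers (Cdh15, 0.16), lists with camera adjusted p of 0.229 and 0.789. The smooth muscle list had 0.622 with 1 of 6 lower, the macrophage list 0.229, the lymphocyte and granulocyte list 0.534, the endothelial list 0.947, the erythroid list 0.947 and the Schwann cell list 0.789.

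Within the BM3 animals all 3000 genes called in TA kept the sign of their change, with 857 higher and 1025 lower. The choice of genes on all arrays favours this too. Within the BM2 and BM2* animals 2942 of the 3000 kept it, with 166 higher and 211 lower.

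**Figure D2:**
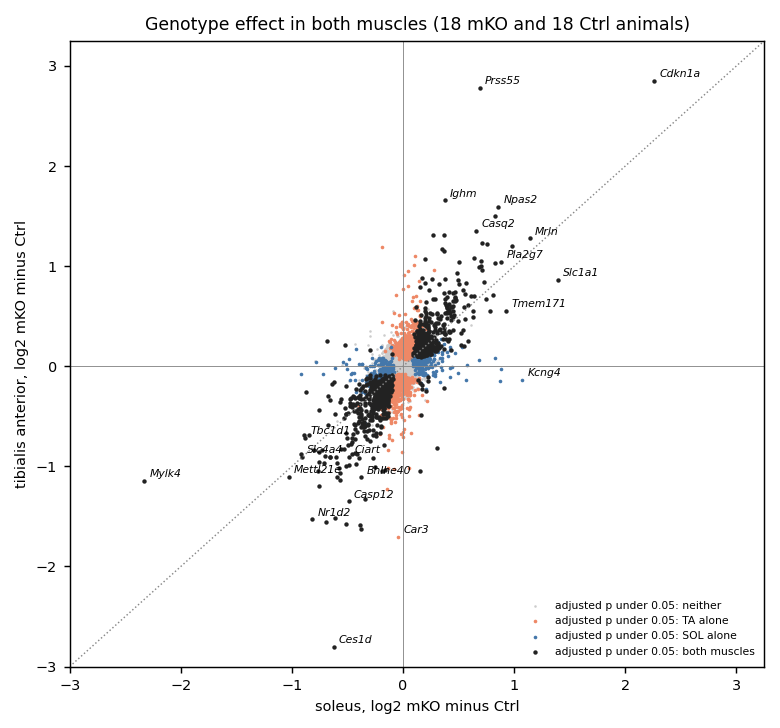
Change in mKO minus Ctrl in TA (log2, vertical) against SOL (log2, horizontal) for each gene. Cdkn1a lies at 2.26 in SOL and 2.85 in TA, and 926 genes called in both muscles share their direction.

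The changes of the muscles overlapped. In both muscles 434 genes were higher, against 48.7 for independent lists, and 492 were lower, against 57.7, while 11 were higher in SOL and lower in TA, against 58.0, and 4 the reverse, against 48.4. Of the 926 genes with a shared direction, 635 had the larger change in TA. The muscles came from the same animals. Across genes, which are not independent replicates, the changes in SOL and TA correlated with r = 0.616, against at most 0.486 when genotypes were exchanged among animals of the same time. A direct test of the difference, within animals, called 549 genes (2372 at an unadjusted p under 0.05, and 1201 with array weights). Of the 549, 151 changed the same way in both and more in TA, 14 the same way and more in SOL, 284 only in TA, 73 only in SOL and 15 in opposite directions. Car3 fell in TA alone (-1.71 against -0.047 in SOL, limma adjusted p of the difference = 4.8e-18), Prss55 rose by 0.69 in SOL and 2.78 in TA (adjusted p = 1.21e-15), and Tmem234, a membrane protein gene, rose in TA alone (0.91 against 0.0040, adjusted p = 6.65e-13). Mical2, which encodes an enzyme that oxidises actin and lies 5 measured genes from the floxed Arntl, fell by 1.05 in TA and was higher by 0.16 in SOL (adjusted p = 1.86e-14), and its SOL call ended without Ctrl ZT4 C, mKO ZT8 A, Ctrl ZT16 C or mKO ZT20 C (adjusted p up to 0.0528). Kcng4 (adjusted p = 2.39e-12), Calb1 (3.7e-07), Pln (0.000222) and Dkk2 (8.11e-06) changed in SOL and differed from TA, where their changes were -0.14, -0.032, -0.14 and -0.078.

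By list, the change in mKO was lower in TA than in SOL for the core clock (camera adjusted p = 3.48e-08, adjusted p = 0.0342 with an estimated correlation) and clock output (2.94e-10, adjusted p = 6.23e-05 with an estimated correlation), with 6 of 15 and 6 of 11 genes more negative (10 and 7 when adjusted over the list alone). In the core clock 2 genes, Npas2 and Bhlhe41, were more positive (3 when adjusted over the list alone, and 1 in clock output). The change of slow fibre genes in mKO was higher in TA than in SOL (1.45e-07, adjusted p = 0.0561 with an estimated correlation), for 3 of 13 over all genes and 7 when adjusted over the list alone. The change of glycolysis (0.0181, adjusted p = 0.183 with an estimated correlation) and of amino acid catabolism (0.0239, adjusted p = 0.373 with an estimated correlation) was also higher in TA, and that of glucose uptake and glycogen lower (0.0239, adjusted p = 0.387 with an estimated correlation).

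**Figure D3:**
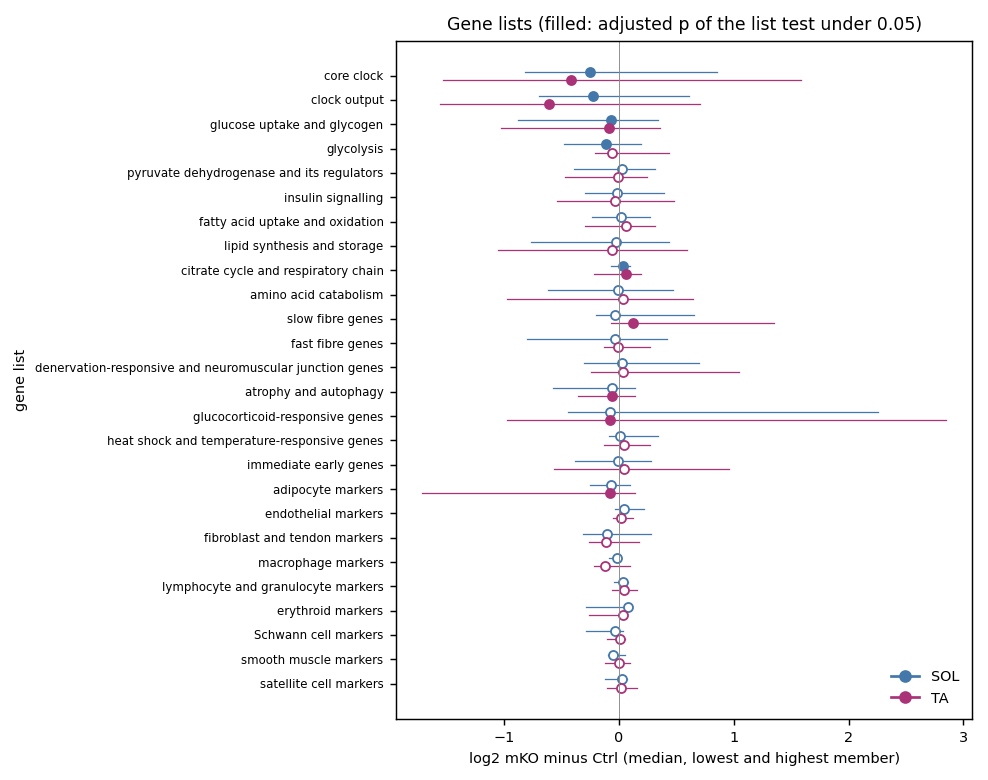
Median log2 change in mKO minus Ctrl of each of the 26 gene lists in SOL and TA (points, filled where the adjusted p of the list test was under 0.05), with lines from the lowest to the highest member. The clock output list has the lowest median in TA, at -0.61.

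In Ctrl animals the muscles differed first in their contractile genes. The slow isoform genes Myl2, Tnnc1, Tnni1 and Myh7 were lower in TA by -6.61 ± 0.077 (SE, n = 18 animals, limma adjusted p = 6.05e-33), -6.41, -6.33 and -6.14, each in 18 of 18 animals. Myh4 and Actn3, genes of the fastest fibres, were higher in TA by 2.77 ± 0.31 (adjusted p = 6.15e-09) and 2.89 ± 0.18 (adjusted p = 1.47e-14). TA was higher for 4636 genes and lower for 4054. Smox, which encodes spermine oxidase, led the genes higher in TA (3.57), followed by Mss51 (3.46), Pla2g7 (3.42), Mstn (3.36), Cyp4f39 (3.23), the myosin-binding protein gene Mybpc2 (2.83), the lactate transporter gene Slc16a3 (2.81) and the calcium buffer gene Pvalb (2.67). The genes lowest in TA also held Lgi1 (-5.72), Tecrl (-5.68), Tnnt1 (-5.59), Tpm3 (-4.95), the slow calcium pump gene Atp2a2 (-4.70) and Myl3 (-4.11).

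All 13 slow fibre genes were lower in TA (camera adjusted p = 3.16e-25, adjusted p = 0.00021 with an estimated correlation) and all 15 fast fibre genes higher (2.1e-14, adjusted p = 0.00724 with an estimated correlation). Glycolysis was higher in TA for 12 of 14 genes (2.9e-10, adjusted p = 0.000368 with an estimated correlation), with Gpd1 at 2.58, while Ldhb was at -2.50. Fatty acid uptake and oxidation was lower for 20 of 22 (1.7e-13, adjusted p = 0.00139 with an estimated correlation), with Lpl at -1.72 and the exception Ucp3 at 1.06. These counts were the same when adjusted over the list alone. A further 7 lists were called with the preset correlation only, which were lipid synthesis (15 of 20 lower, 3 higher, Dgat2 -2.14; 8.86e-05, 0.203 with an estimated correlation), adipocyte markers (7 of 9 lower, Adipoq -1.24; 9.8e-05, 0.077), fibroblast and tendon markers (7 of 11 lower, 1 higher, Comp -1.27; 0.00263, 0.334), insulin signalling (12 of 22 lower, 4 higher, Grb10 -1.03; 0.00799, 0.3), neuromuscular junction genes (9 of 17 lower, 6 higher, Chrna1 -1.61; 0.0127, 0.248), clock output (6 of 11 higher, Tsc22d3 1.15; 0.0352, 0.139) and heat shock genes (6 of 15 lower, 1 higher, Hspa1a -2.52; 0.0352, 0.139). Among lists not called, glucose uptake and glycogen (0.0696) held Phkg1 at 2.19 and Tbc1d4 at -1.82, amino acid catabolism (0.705) Gpt2 at 2.12, the citrate cycle (0.941) Idh2 at -2.13, and Schwann cell markers (0.117) Pmp22 at -0.96. The median and mean differed in sign for the pyruvate dehydrogenase, citrate cycle, amino acid, atrophy and Schwann cell lists.

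Over the day, a 24 h cosine called 1224 rhythmic genes in SOL of Ctrl and 547 in TA of Ctrl. With time as a factor these were 713 and 335, and without ZT20 SOL of Ctrl had 803. The clock genes stood among the strongest. In SOL of Ctrl Nr1d1 had an amplitude of 1.43 ± 0.094 log2 units (SE, n = 18 animals, limma adjusted p = 1.05e-12) and peaked at ZT 6.95, Per2 0.93 at ZT 13.6, Dbp 1.11 at ZT 11.4 and Npas2 1.29 at ZT 1.41. In TA of Ctrl Nr1d1 had 1.17 ± 0.051 (adjusted p = 3.13e-17) at ZT 5.86, Ciart 1.34 at ZT 10.4 and Per1 1.27 at ZT 11.7. Outside the clock, Ppp1r3c (0.98, ZT 22.3), Lrrc30 (0.76, ZT 22.4), Dyrk2 (0.69, ZT 22.6) and Tspan4 (0.69, ZT 12.5) were among the genes with the smallest p in SOL, and the kinase gene Pim1 (0.81, ZT 23.8), the lipid droplet gene Pnpla3 (0.58, ZT 21.8), Wsb1 (0.63, ZT 23.7) and Zfp462 (0.39, ZT 0.478) in TA. The median amplitude of rhythmic genes was 0.21 in SOL and 0.25 in TA, with 84 and 52 genes over 0.5. The median SE of their peak times was 0.829 h in SOL and 0.775 h in TA. The smaller peak error in the simulation is an absolute error at amplitudes of 0.25 to 1, so these are unlike measures. In both muscles 325 genes were rhythmic, against 33.1 for independent lists, and 252 of these peaked within 2 h of each other.

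By list, 13 of 15 core clock genes were rhythmic in SOL of Ctrl (one-sided Fisher's exact test, adjusted p = 3.33e-13) and 12 in TA (1.48e-15), and 8 of 11 clock outputs in SOL (2.12e-07) and 9 in TA (4.91e-12). Glucocorticoid-responsive genes were rhythmic for 12 of 16 in SOL (4.29e-11) and 10 in TA (1.15e-11), and lipid synthesis for 7 of 20 (0.000728) and 6 (6.89e-05). Insulin signalling was called in both (6 of 22, 0.00579, and 5, 0.00111), as were neuromuscular junction genes (6 of 17, 0.00174, and 3, 0.0328) and endothelial markers (4 of 9, 0.00568, and 4, 0.00031). Atrophy (5 of 17, 0.00874) and fatty acid genes (5 of 22, 0.0257) were called in SOL and immediate early genes (3 of 16, 0.0314) in TA. Adjusted over the list alone, the counts in SOL and TA were 13 and 12 for the core clock, 9 and 9 for clock output, 12 and 10 for glucocorticoid-responsive genes and 9 and 10 for lipid synthesis.

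Rhythms persisted in the muscles of mKO, with 1149 genes called in SOL and 357 in TA. With time as a factor these were 565 and 214, without ZT20 SOL had 579, and with array weights TA had 563. The arrays measured whole muscles while Cre acts in muscle fibres, so rhythms of fibres and of other cells cannot be told apart. Endothelial markers were the only called list of other cell types (4 of 9 in SOL, one-sided Fisher's exact test, adjusted p = 0.00416, and 3 in TA, 0.00274). Glucocorticoid-responsive genes were called as well (10 of 16 in SOL, 2.55e-08, and 6 in TA, 2.59e-06). Both clock lists were called too. In SOL immediate early (6 of 16, 0.00105), lipid synthesis (6 of 20, 0.00334) and fatty acid genes (6 of 22, 0.00416) were called. So were neuromuscular junction (5 of 17, 0.00663), insulin signalling (5 of 22, 0.0198) and atrophy genes (4 of 17, 0.0354). In TA heat shock (3 of 15, 0.011), glucose uptake and glycogen (3 of 20, 0.0215) and insulin signalling (3 of 22, 0.0243) were called. Lipid synthesis in TA had 1 of 20, against 6 in Ctrl. In SOL of mKO Nr1d1 kept an amplitude of 1.40 ± 0.094 (SE, n = 18 animals, limma adjusted p = 2.69e-12), and Per3 (0.89), Nr1d2 (0.73), the metalloprotease gene Adamts1 (0.88), Otud1 (1.28), Slc46a3 (0.35) and Pdcd4 (0.68) were called. In TA of mKO Nr1d1 had 0.75 ± 0.051 (adjusted p = 2.91e-11), Per2 0.62, the uncoupling protein gene Ucp3 0.88, Osgin1 0.38 and Gstt2 0.44. In SOL 632 genes were rhythmic in both genotypes, with 525 peaks within 2 h, and in TA 183, with 149 peaks within 2 h. The median amplitude over the core clock list went from 0.75 to 0.59 in SOL and from 0.38 to 0.30 in TA, with 12 and 8 of 15 genes rhythmic in mKO (12 and 11 when adjusted over the list alone). Over clock output it went from 0.50 to 0.38 and from 0.32 to 0.15. In SOL of mKO the largest share of peaks, 32.2%, fell nearest ZT8, against 19.7% in Ctrl. In TA of mKO 32.2% fell nearest ZT16, against 16.6% in Ctrl. These peaks were fitted without the identification series as a block, and its spread over the times differed between Ctrl and mKO. A shift of peaks therefore cannot be told apart from a difference between series.

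**Figure D4:**
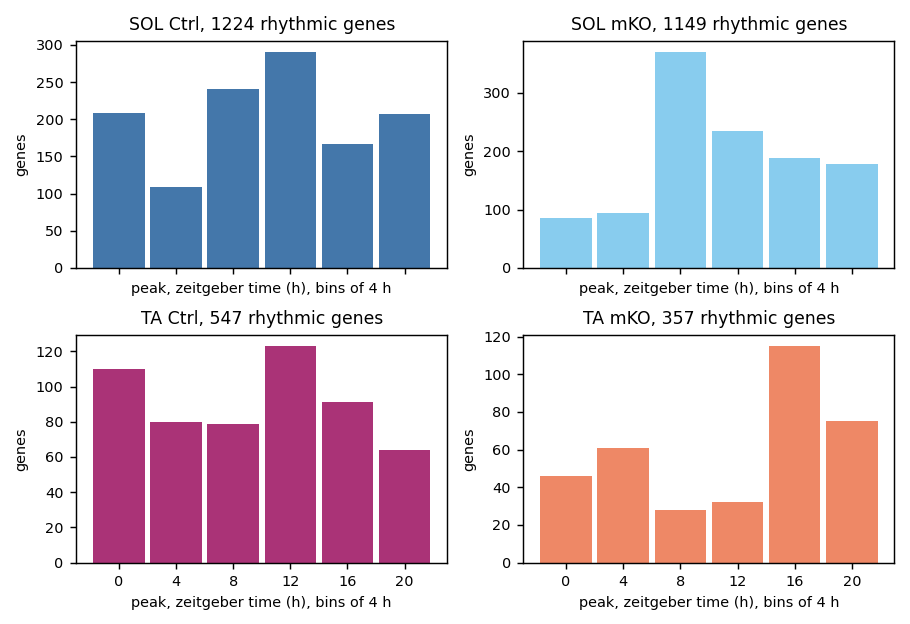
Number of rhythmic genes (vertical) with their peak nearest each Zeitgeber time (h, horizontal) in each group of muscle and genotype. In SOL of mKO 370 of 1149 genes peak nearest ZT8, and in TA of mKO 115 of 357 peak nearest ZT16.

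In the test of a difference in rhythm between genotypes, 1065 genes in SOL and 680 in TA had an unadjusted p under 0.05. A share of 0.05 of the 20239 genes would pass this limit without any difference, so these counts are no evidence of many changed genes. After adjustment 8 genes were called in SOL and 21 in TA, all with a smaller amplitude in mKO. In SOL these were Arntl, Lrrc30 (0.76 to 0.21, limma adjusted p = 4.79e-05), the retinoid receptor gene Rxrg (0.38 to 0.083, adjusted p = 0.000616), Ptpn4 (0.45 to 0.16), Tbc1d1 (0.37 to 0.048), the magnesium transporter gene Slc41a3 (0.55 to 0.22), Dyrk2 (0.69 to 0.31) and Ppp1r3c (0.98 to 0.67). The calls of Arntl, Lrrc30 and Rxrg held whichever animal was left out. Those of Ptpn4 (without mKO ZT16 B or mKO ZT16 C, adjusted p up to 0.0539), Tbc1d1 (without any of 5 animals, up to 0.0681), Slc41a3 (7 animals, up to 0.0724), Dyrk2 (14 animals, up to 0.102) and Ppp1r3c (25 animals, up to 0.154) ended without single animals. The count was 3 without mKO ZT16 B or mKO ZT16 C, 4 without Ctrl ZT16 C and 13 without Ctrl ZT16 A. In TA the difference was called for Arntl, Ciart (1.34 to 0.22, adjusted p = 0.00101), Cry2 (0.38 to 0.039, adjusted p = 0.000346), Per1 (1.27 to 0.78), Nr1d1 (1.17 to 0.75), Pnpla3 (0.58 to 0.14), Pim1 (0.81 to 0.46), Slc16a9 (0.63 to 0.11), Ypel2 (0.63 to 0.12), Slc38a4 (0.45 to 0.12) and Coq10b (0.45 to 0.11) among others, and these calls held whichever animal was left out. Without ZT20 the count was 3 in SOL and 10 in TA, and in SOL it was 4 with time as a factor, 13 with array weights and 14 among genes above the median level. Core clock genes were over-represented among the TA calls (5 of 15, 10 when adjusted over the list alone, one-sided Fisher's exact test, adjusted p = 5.59e-11), and glucose uptake and glycogen genes among those of SOL (2 of 20, 3 when adjusted over the list alone, adjusted p = 0.000673). The last rests on Tbc1d1 and Ppp1r3c, whose calls end without single animals.

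The rhythm differed between the muscles of Ctrl for 106 genes, 74 with the larger amplitude in SOL and 32 in TA. The count was 65 without Ctrl ZT12 C and 68 without Ctrl ZT20 B. It was 57 without the pairing of muscles, 38 without ZT20, 33 with time as a factor and 161 after quantile normalisation. Tmem171 had an amplitude of 1.15 ± 0.081 in SOL and 0.11 ± 0.066 in TA (SE, n = 18 animals, limma adjusted p = 2.44e-09), and Pim1 0.13 in SOL and 0.81 in TA (adjusted p = 1.06e-07). The arrestin gene Arrdc3 peaked at ZT 11.9 in SOL and ZT 17.1 in TA, Rnf122 at ZT 5.76 and ZT 21.6, and the RNA-binding Cpeb1 at ZT 10.4 and ZT 1.07. The Wnt receptor gene Fzd9 had 0.64 in SOL and 0.068 in TA, Slc41a3 0.55 and 0.17, and Spsb4 0.47 and 0.035. Core clock genes were over-represented (5 of 15, 8 when adjusted over the list alone, one-sided Fisher's exact test, adjusted p = 2.68e-07), with weaker excesses for clock output (2 of 11, 0.0188), fatty acid (2 of 22, 0.0305), neuromuscular junction (2 of 17, 0.0228) and immediate early genes (2 of 16, 0.0228).

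The identification series were not spread evenly over the times (ZT0 and ZT4 held only BM3 animals, ZT12 none). In Ctrl, BM2 and BM2* animals came only from ZT8, ZT12 and ZT16, so a difference between series can look like a rhythm there. At ZT16 the mKO animals were all BM3 and 2 of the 3 Ctrl animals BM2*. At ZT20 the Ctrl animals were all BM3 and the mKO animals all BM2, and rhythms were not fitted within a series. With the series as a block 876 genes were rhythmic in SOL of Ctrl, 1023 in SOL of mKO, 398 in TA of Ctrl and 385 in TA of mKO, and the rhythm differed by genotype for 6 genes in SOL and 20 in TA and by muscle for 75.

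**Figure D5:**
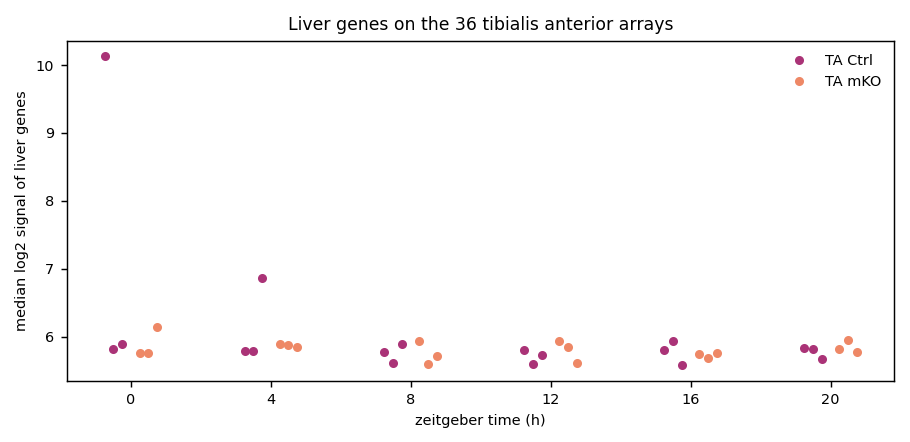
Median log2 level of 27 liver genes (vertical) on each of the 36 TA arrays against Zeitgeber time (h), with Ctrl and mKO in different colours. The array of Ctrl ZT0 replicate A lies at 10.1, and the next highest at 6.86.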

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

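The tests of liver RNA and of array quality, the tests on the neighbours of Myl1 and Arntl, the tests of why TA gave more calls and the test of what the largest splits follow were chosen only after the result was seen, while the count of genes lower in TA without the liver-like array and the other splits of the samples were set before.

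The genotype effect differed between SOL and TA for 549 genes in a test of the difference within animals (limma, adjusted p below 0.05), and among the genes named here each value is the change in TA minus the change in SOL, in log2 units. Clock genes and their outputs moved further down in TA for Bhlhe40 (-0.74), Nr1d2 (-0.71), Nr1d1 (-0.48), Per1 (-0.47), Per3 (-0.45), Rora (-0.23), Dbp (-0.86), Hlf (-0.51), Usp2 (-0.42), Wee1 (-0.32), Tsc22d3 (-0.29) and Tef (-0.24), while Npas2 (0.74) and Bhlhe41 (0.38) differed upward. Further genes with a lower value in TA were Ces1d (-2.17), Car3 (-1.66), Aebp1 (-1.25), Kcng4 (-1.21), Mical2 (-1.20), Maob (-1.19), Nkain1 (-1.06), Pln (-1.01), Sorbs3 (-0.99), Calb1 (-0.91), Cntfr (-0.90), Casp12 (-0.86), Slc1a1 (-0.53) and Tmem171 (-0.37). Genes with a higher value in TA were Prss55 (2.09), Ighm (1.28), Mylk4 (1.19), Dupd1 (1.04), Ttll7 (0.95), Tmem234 (0.91), Dkk2 (0.84), Casq2 (0.70), Actc1 (0.67), Nos1 (0.62), Cdkn1a (0.59), Tead4 (0.52) and Olfm1 (0.22).

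The rhythm of Ctrl differed between the muscles for 106 genes in a test of the difference within animals, and for 65 without Ctrl ZT12 C and 68 without Ctrl ZT20 B. The amplitude of the difference was 0.45 for Nr1d1, 0.34 for Per3, 0.33 for Arntl, 0.32 for Nr1d2, 0.47 for Bhlhe41, 0.37 for Nfil3, 0.27 for Tef, 1.04 for Tmem171, 0.68 for Cpeb1, 0.68 for Fzd9, 0.68 for Pim1, 0.61 for Arrdc3, 0.58 for Rnf122, 0.47 for Spsb4, 0.43 for Metrnl, 0.38 for Slc41a3 and 0.35 for Fam53b. Among probe sets with no gene name, which the comparisons left out, 69 passed the threshold for the genotype effect in SOL and 137 in TA.

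Liver transcripts were high on the TA array of Ctrl ZT0 A, where Alb, Serpina1a and Mup3 were seen first and belong to the liver list. The 27 measured liver genes lay a median of 4.27 log2 units above the other 2 arrays of the group, each higher than on every other TA array, which is what liver RNA in the sample predicts, and no biological explanation was tested. Of 10000 random lists of the same mean level 0 had a median as high (highest 0.12), so the excess was particular to the liver list. That cannot decide on lower quality of the array, because the list was written after liver transcripts had been seen there. The array also lay farther from the other 2 of its group than any other array did (root mean square 0.408 log2 units). Liver RNA as the source of the genes lower in TA of mKO is argued against, since 1476 genes were lower without that array, against 1631 with it, and 1448 were in both lists. A second Ctrl array of TA, ZT4 C, lay at 6.86 for the liver genes, against 5.79 and 5.80 in its group, and without that animal 1248 genes were higher and 1548 lower in TA.

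Genes beside Myl1, whose promoter drives Cre, changed with genotype in both muscles, among them Lancl1 (-0.34 in SOL, -0.60 in TA), Kansl1l (-0.22 and -0.52) and Mreg (-0.46 and -0.88), named after their values were seen. Without these 3 genes, which prompted the test, 10.6% in SOL and 25.5% in TA of the 47 other nearest genes were called, at the percentiles 82.9 and 93.6 of 19231 such windows, against 95.9 and 98.4 with them, so DNA linked to a Cre locus at Myl1 cannot be told apart from a response to the loss of Bmal1. For the floxed Arntl the lower percentile was 82.9 as well (12.0% in SOL, 28.0% in TA), and linked DNA cannot be told apart there either, because the percentile was above 95 in TA alone. The insertion site of Cre is not given in the sources used here, so the first explanation assumes Myl1. Myl1 itself was lower in mKO at 6 of 6 times in both muscles, and whether this comes from a Cre locus was not tested. The 3 genes were taken out of the Myl1 window while called genes stayed in all other windows, which lowers its percentiles.

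TA gave 3000 calls and SOL 1436. A smaller spread between TA arrays is argued against, since the median standard error was larger in TA by 0.0034, and so is the identification series, since the ratio of calls within BM3 animals was 3.25, against 2.09 in all. More Cre in TA cannot be told apart from other causes, because Myl1 differed by 0.09 (0.0863, SE 0.035, limma adjusted p = 0.0493) at the 99.9 percentile of level, where arrays resolve little. A difference between fibre types in the response to Bmal1 stays open as untested.

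Other splits of the samples were drawn, 100 for each comparison with the real one included. The share of splits that reached the real count was under 0.05 in each comparison. Chance can be excluded at that share except for rhythm differing by genotype, where single other splits gave far more genes than the real one. For the genotype effect 1 split, the real one, reached 1436 genes in SOL (highest other 116), 3000 in TA (114) and 549 in the interaction (2). For the tissue difference it was 1 with 8690 genes (highest other 2868). For rhythm it was 1 each with 1224 in SOL of Ctrl (11), 1149 in SOL of mKO (3), 547 in TA of Ctrl (23) and 357 in TA of mKO (3), and 1 with 106 for rhythm differing by muscle (17). For rhythm differing by genotype 3 splits reached the 8 genes of SOL (highest other 513) and 2 the 21 genes of TA (highest other 1462). What made those splits large was not found, so chance is not excluded for the counts of 8 and 21 genes. The splits compare counts and do not test single genes. The largest splits did not follow the real genotype over the day more than others did. The 24 h amplitude of the number of real mKO animals in the split's mKO group was 0.333 for the largest split in SOL, as large in 91 splits. It was 0.577 for that in TA, as large in 48.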

How the results depend on the processing

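Leaving out the TA array with liver transcripts or 4 TA arrays was chosen only after the data were seen, and all other alternatives before. Of 469 called results for named genes, 336 kept direction and call under every alternative run for them, leaving out single animals not counted. Most alternatives apply to some results only. Of 9930 values compared, 9500 kept their side of the threshold, and where called their direction, while 290 lost and 138 gained the call and 2 turned. The sign of values that stayed uncalled was not compared.

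Fewer animals gave fewer calls by construction. Among BM3 animals alone SOL had 239 genes higher and 340 lower and TA 857 and 1025, and among BM2 and BM2* animals alone 86 and 81, and 166 and 211. Of the 1436 genes called in SOL and 3000 in TA, 1436 and 3000 kept their sign among BM3 animals and 1417 and 2942 among the others, which selection on all arrays favours. Arntl turned or moved with the sampled times, which differ between the series: 0.73 in SOL and 0.71 in TA among BM2 and BM2* animals, both past the threshold, and -0.27, not past it, in SOL and -0.47, past it, in TA among BM3 animals. In BM2 and BM2* animals Ldhb in TA was -0.048 (adjusted p = 0.977) and Retn in TA 0.068 (adjusted p = 0.948), both turned, and the cause was not tested.

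Array weights raised TA to 2773 genes higher and 2615 lower, the interaction to 1201, rhythm in TA of mKO to 563 and rhythm differing by genotype in SOL to 13, and the cause was not tested. Time as a factor, which spends more terms, left 713 rhythmic genes in SOL of Ctrl, 565 in SOL of mKO, 335 in TA of Ctrl and 214 in TA of mKO, 4 genes with rhythm differing by genotype in SOL and 33 with rhythm differing by muscle. Without ZT20, with fewer samples, these were 803 and 579 rhythmic genes in SOL of Ctrl and mKO, 3 and 10 genes differing by genotype in SOL and TA, and 38 by muscle. Genes above the median level alone, with fewer genes tested, gave 14 genes differing by genotype in SOL and 3 lists called in SOL in place of 5. Quantile normalisation gave 161 genes with rhythm differing by muscle, and the cause was not tested.

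Without each animal in turn the counts were 640 to 790 higher and 655 to 759 lower in SOL, 1196 to 1654 and 1449 to 1915 in TA, 4408 to 4695 and 3873 to 4121 between tissues, 485 to 611 in the interaction, 1023 to 1270, 854 to 1338, 465 to 625 and 255 to 389 for rhythm in SOL of Ctrl and mKO and TA of Ctrl and mKO, 3 to 13 and 18 to 26 for rhythm differing by genotype in SOL and TA, and 65 to 117 by muscle. Lists called ran from 4 to 8 in SOL, 7 to 8 in TA, 10 to 11 between tissues and 4 to 8 in the interaction, and Arntl from 0.07 to 0.13 in SOL and from -0.11 to -0.04 in TA.

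The labels do not say that the replicate letters pair animals, and they were not used as pairs because not every pair of mKO and Ctrl of the same letter correlated over 0.1: 9 of 18 did in SOL (median r 0.084, -0.28 to 0.239) and 12 of 18 in TA (0.161, -0.136 to 0.322). As a hint that letters share something, 18 and 22 of 36 arrays were closest to their own letter, against 12 by chance. With the letter as a block the counts were 731 and 718 in SOL, 1778 and 1902 in TA, 1293 and 1209 for rhythm in SOL, 588 and 394 in TA, 6 and 22 for rhythm differing by genotype, lists 6 and 8, and Arntl 0.09 and -0.07. Without the pairing of muscles within animals 4675 and 4046 genes differed between tissues, 577 in the interaction and 57 in rhythm by muscle. Without the liver-like array the TA counts were 1225 and 1476, and without 4 TA arrays 1480 and 1992. Dim genes near background limit what the arrays resolve.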

Other observations

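The gene Nnt, chosen after its values were seen, fell into 2 groups of animals. In SOL of Ctrl 11 animals lay at 10.45 to 10.92 log2 units and 7 at 11.41 to 11.73, and in SOL of mKO 10 lay at 10.74 to 11.07 and 8 at 11.50 to 11.89. In TA of Ctrl 11 lay at 7.21 to 8.02 and 7 at 8.90 to 9.63, and in TA of mKO 10 lay at 7.96 to 8.59 and 8 at 9.40 to 10.12. In each genotype 18 of 18 animals were on the same side of the gap in both muscles. The genotype effect on Nnt was 0.23 ± 0.14 in SOL (SE, limma adjusted p = 0.476) and 0.58 ± 0.22 in TA (adjusted p = 0.085). Below the gap were 12 of 23 BM3 animals, 6 of 7 BM2* animals and 3 of 6 BM2 animals.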
